A study of Mus musculus with 4 samples.

How the data were processed

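Spatial gene expression was measured with the 10x Genomics Visium assay on ovary sections of outbred CD-1 mice. Per the labels' protocols, ovaries were embedded and frozen, cut at 10 µm, placed on capture areas of 6.5 mm, fixed, stained and permeabilised for 18 minutes. The design held 4 capture areas, each with 1 young (3 to 4 months) and 1 aged (15 to 16 months) section, and 4 animals per age. The deposited tables hold raw UMI counts per gene and spot, with no normalization, as the whole numbers and the differing totals per spot show. Other deposited files give array and pixel positions (other units, per the labels and the files' layout) and image scale factors, which were not used here. Per the submitters' processing notes, Space Ranger 1.2.1 and the mouse build mm10 were used; their annotation, filters and the counting's use of strand are not given in the sources used here. Gene positions came from GENCODE release M21 (mm10), joined by symbol. Genes with near-identical copies, such as haemoglobins, MHC class I genes and immunoglobulin genes, share reads, so that their single values are uncertain.

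The tables held 32285 genes and 4191 spots. The position files marked 4263 spots as over tissue, of which 72 had no column in the tables and were left out. Each spot was assigned to the young or aged section from the sides that the labels give (bottom or left for young, top or right for aged), by splitting positions at the widest gap in the middle 60% of their range. Small pixel rows were taken as the top and small pixel columns as the left, so that an image turned against the labels would exchange the ages within an area, which the files cannot show. Expression was never used for the assignment. Area 3 ran against the other areas in its share of spots with oocyte transcripts (0.384% in the young and 18.2% in the aged section). It ran with them in number of spots, UMIs per spot and mitochondrial share, so that an exchange there stays open. The nearest spots of the sections of an area lay 3.46 spot spacings apart, and splitting by k-means with 2 centres moved 11 spots.

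Counts were summed over the spots of each section, since animals and not spots are the replicates, and compared with edgeR 4.0.16 quasi-likelihood tests (limma 3.58.1, R 4.3.3; TMM scaling, filterByExpr, Benjamini-Hochberg threshold of 0.05). CPM of genes were computed from these sums over the total counts, without TMM factors. Log2 fold changes, aged over young with the standard error of the fit, used TMM scaling, as did log2 CPM in correlations and list tests. The ratio of printed CPM can therefore differ from the fold change. The number of a capture area pairs its sections, and a check on whole sections gave correlations across genes of 0.00358, 0.165, −0.224 and 0.208 between paired sections after the mean of each age was removed. Within regions the correlations of all pairs tested were positive, at 0.0422 to 0.424 in S1, 0.0977 to 0.191 in S2, 0.0126 to 0.250 in S3 and 0.0464 to 0.246 in S8. The fit had age alone in every comparison, as set before the data were examined, and the capture area entered as a block in an alternative, which in S2 and S8 keeps only sections with a partner. The scaling moved the median of all genes by 0.0128 (TMM), 0.0169 (RLE) and −0.00516 (library size). The median of no called list changed sign between these scalings in whole sections, or between TMM and RLE in regions, where library size alone was not run.

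Regions were formed in scanpy 1.11.5 (Python 3.11.15) from spots with at least 500 UMIs (18 spots were under this) and genes in at least 10 spots, scaled to 10000 per spot, log-transformed, with 2000 variable genes. Values were centred and scaled with a limit of 10, and 30 principal components, 20 nearest neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6) with a fixed seed gave the regions. Centring within capture areas at resolution 0.6 gave 22 regions (A1 to A22), of which 0 had at least 15 spots in at least 3 sections per age. Centring within sections at resolution 0.4 gave 16 regions (S1 to S16), chosen after resolutions 0.2, 0.3 and 0.4 had been seen, and 4 of these met the minimum. Centring within a section removes differences between sections from the clustering, though not from the counts that were then compared. Of the spots of S2, 33.3% in young and 1.90% in aged sections lay in region A2 and 0.402 and 25.3% in A21, led by oviduct epithelium genes. Of those of S8, 73.9 and 76.5% lay in A10, and 8.11 and 21.2% in A22, led by smooth muscle genes. A2 held 14.4% of the young but none of the aged S8 spots. Region counts were summed per section and tested as for whole sections, and an interaction term with sections as a factor tested whether the age difference differed between a region and the rest of the section. In S8 the aged group had 3 sections, and in S2 both groups had 3.

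The gene lists, 17 of cell type markers and 18 of processes, the tests, the rule for named genes and the alternatives were fixed before the data were examined, apart from the section-centred regions and the additions named in the closing part. Lists with at least 4 measured members were tested with camera (correlation 0.01) on voom-weighted log2 CPM (prior count of 2), adjusted over lists, or over lists and regions together (114 tests, of which 40 were called). Camera with an estimated correlation and fry gave further values, as the preset correlation is lower than that of many lists. Several lists share members, such as the steroidogenesis, granulosa and cholesterol lists.

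The rule for named genes took, per comparison, up to 10 rises and 10 falls among passing genes (5 and 5 in regions) with mean CPM of at least 10 (20 in regions) and no overlap between ages. It also took up to 4 members of each list with the smallest p (2 per called list in regions), and the 5 genes with the smallest p where fewer than 5 passed. Unnamed gene models were not named. Of the 234 entries that the rule takes, 148 are members of called lists or genes with the smallest p, and the text names some of these, a narrowing chosen after values were seen, together with Fabp4 and genes that passed in an alternative.

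Per section, the number of spots, median UMIs, median genes, and mitochondrial and ribosomal shares were compared by exact permutation of the 70 assignments of 8 sections (scipy 1.17.1, pandas 2.3.3, two-sided), as were region shares. For the share of spots with oocyte transcripts, spots were thinned to 2000 UMIs and counted with at least 3 UMIs of the oocyte list, and spots under 2000 UMIs were left out. Where a group had no counts, the fold is a bound against 3 counts over the group, which covers counting error only.

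The tests were tested on simulated data with the sections' depths and a trended dispersion, with independent genes. At folds of 2, 4 and 8 they found 44.8, 82.1 and 93.9% of changed genes in whole sections, with 4 false calls among 13851 genes. In region S1 they found 40.3, 92.5 and 95.5%, in S2 35.8, 88.1 and 92.4%, in S3 46.3, 94.0 and 92.4%, and in S8 20.9, 80.6 and 87.9%. Camera called 1 changed list and 0 unchanged lists among 31 simulated lists. Since the simulated genes were independent, this does not test false calls of lists whose members vary together.

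Alternatives were the capture area as a block, RLE scaling, library size alone, DESeq2 1.42.0, no filter on low counts, each section left out, spots of at least 2000 UMIs, counts thinned to the shallowest section, limma on region means with equal weight, other resolutions and centrings, and sign flips within areas. The limma fit averaged only S1 and S3, the 2 regions tested in every section, so that it leaves out all other spots. Images of the sections were not analysed here. Figures were drawn with matplotlib 3.10.9.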

Results

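Gene expression was measured across sections of mouse ovary by spatial transcriptomics, in which RNA leaving a frozen section is caught on an array of barcoded spots. Outbred CD-1 females of 3 to 4 months (young) or 15 to 16 months (aged) each gave 1 section, with 4 animals per age. Every one of the 4 capture areas held 1 young and 1 aged section, so that both ages shared a library in each area, and the pairs are numbered 1 to 4 here. The comparison asks which transcripts, tissue regions and cell types of the ovary differ with the age of the animal. Sections in the young group held 532, 730, 542 and 762 spots in the order of their areas, and aged sections held 299, 653, 257 and 416. Total counts of unique molecules (UMIs) were 11341189, 21619232, 9702600 and 17274020 in the young sections and 5065830, 9506517, 2777948 and 7915434 in the aged sections. A spot covers several cells, so that no value below belongs to a single cell. Across genes, which are not independent replicates, log2 CPM (a gene's counts scaled to a fixed section total) of whole sections correlated at 0.925 to 0.963 between young sections, 0.886 to 0.955 between aged sections and 0.909 to 0.958 between the sections of an area.

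Aged sections gave fewer UMIs and fewer genes per spot than young sections. The median spot held 20384 ± 5543 UMIs in young sections and 12692 ± 2725 in aged sections (mean ± SD of the section medians, n = 4 per age). The aged section was the lower of the pair in 4 of 4 areas. The median number of genes per spot was 5701 ± 424 against 4406 ± 471. Mitochondrially encoded transcripts, whose share of a spot's RNA is commonly read as a sign of tissue state, took 0.636 ± 0.241% of UMIs in young sections and 2.00 ± 1.44% in aged sections, with the highest share, 3.86%, in aged section 3. Transcripts of ribosomal proteins took 14.0 ± 4.07% and 14.0 ± 1.90%. By exact permutation tests (two-sided, the smallest possible p being 0.0286 with n = 4 per age), p was 0.0286 for UMIs and for genes per spot, 0.0571 for the mitochondrial share, 0.0857 for the number of spots and 1 for the ribosomal share. After adjustment over the 5 measures (Benjamini-Hochberg) no measure passed: p was 0.0714 for UMIs and genes, 0.0952 for the mitochondrial share and 0.107 for the number of spots. Without aged section 2, the adjusted p was 0.0476 for genes per spot, for the mitochondrial share and for the number of spots (exact permutation tests). With any other section left out, no measure passed. The adjusted p of these tests was then 0.0714 to 0.143 for genes, 0.0952 to 0.25 for the mitochondrial share and 0.179 to 0.25 for the number of spots.

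**Figure D1:**
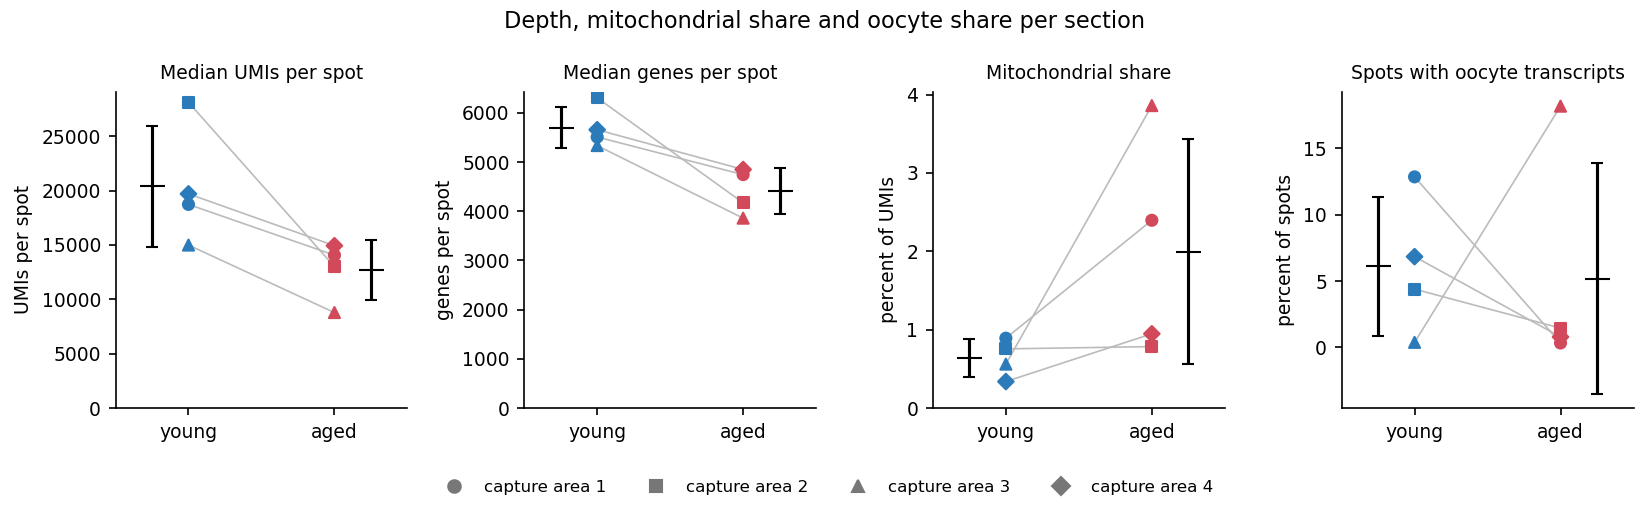
Median UMIs per spot, median genes per spot, mitochondrial share of UMIs (percent) and share of spots with oocyte transcripts (percent) in each of the 8 sections, with lines joining the sections of a capture area and bars giving mean ± SD per age. The aged section had fewer UMIs per spot in 4 of 4 areas, and aged section 3 had the highest mitochondrial share (3.86%) and stood apart in its share of spots with oocyte transcripts (18.2%).

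Regions of the sections were defined by grouping spots on their expression and are called by number and by their leading genes. With spots centred within each capture area, as chosen before the data were examined, 22 regions formed, and none had enough spots in 3 sections of each age for a gene test. A further 16 regions, S1 to S16, were therefore formed with spots centred within each section, a choice made after seeing the data, and 4 of them could be tested. Region S1 (1327 spots) was led by Ccl21a, a chemokine, and Agt, angiotensinogen. Region S2 (407 spots) was led by the oocyte genes Ooep, Zp3, Padi6 and Gdf9, with 6 of its 10 leading genes on the oocyte list. Region S3 (387 spots) was led by Inhba, Inhbb and Nppc, with 5 of 10 on the granulosa list. Region S8 (196 spots) was led by Upk3b, Krt19, Lhx9 and Lgals7, with 3 of 10 on the surface epithelium list.

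**Figure D2:**
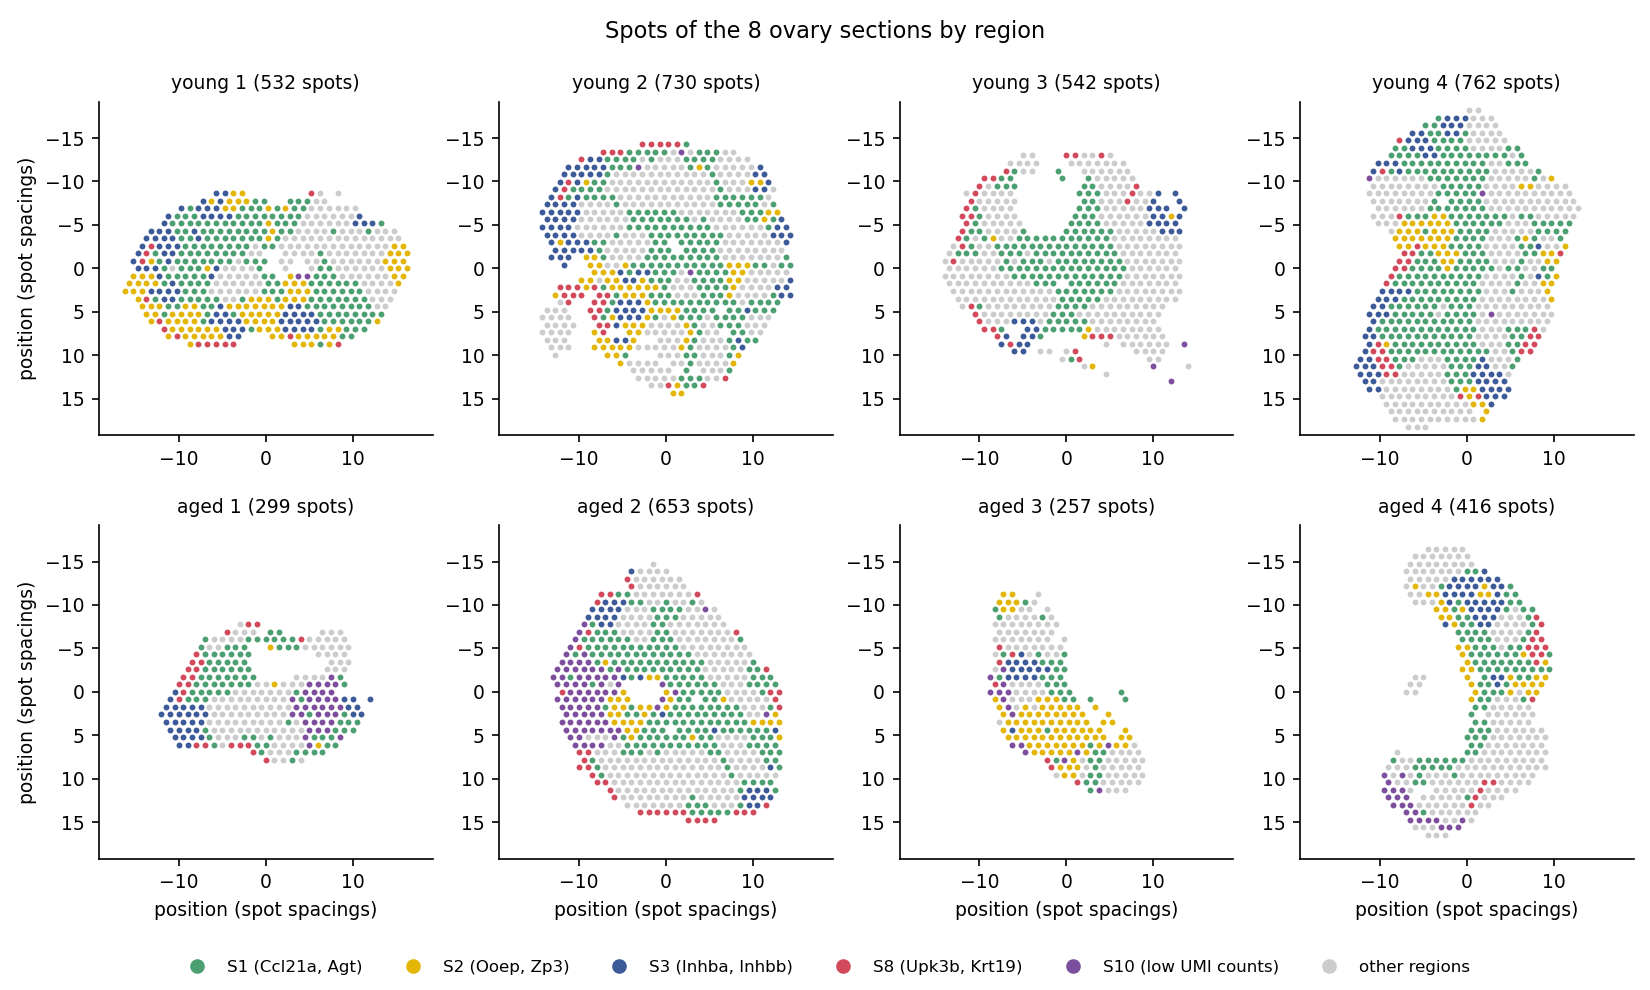
Position of every spot in the 4 capture areas, in spot spacings along both axes, coloured by region, with S1, S2, S3, S8 and S10 each in a colour of its own and all other regions in grey. S1 held 34.0 ± 4.44% of the spots of a young section and 26.0 ± 7.70% of an aged one, and S10 held 0.434 ± 0.0823% and 8.86 ± 3.49%.

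In whole sections, no gene passed the test between ages, and the genes with the smallest p differed as follows. Calb2, which encodes the calcium-binding protein calretinin (chr8, 110137502 to 110168210 in mm10), was at 0.289 ± 0.0966 CPM in young and 2.66 ± 1.24 CPM in aged sections (log2 fold change 3.15 ± 0.46, SE, n = 4 per age). In limma on the mean of regions S1 and S3 alone, its log2 fold change was −0.24. Col4a4, a type IV collagen chain of basement membranes (chr1, 82448423 to 82586849), was at 30.8 ± 9.22 and 12.8 ± 3.81 CPM (−1.26 ± 0.23). BC048679 (chr7, 81494275 to 81498281) was at 0.554 ± 0.468 and 16.7 ± 20.2 CPM, with 46.8 CPM in aged section 3. Ttyh2, a chloride channel gene (chr11, 114675431 to 114720977), was at 62.8 ± 8.76 and 107.5 ± 9.28 CPM. Itih2, whose product binds hyaluronan (chr2, 10094593 to 10131396), was at 14.7 ± 6.45 and 4.13 ± 0.643 CPM. In edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment, 0 of 14044 genes passed the threshold of 0.05, with 392 at an unadjusted p under 0.05 and a lowest adjusted p of 0.823. With the capture area as a block the count was 0 (435 unadjusted), and limma on the mean of regions S1 and S3 alone gave 0 (676 unadjusted). DESeq2 passed 6 genes, of which BC048679, Calb2 and Ttyh2 were higher and Col4a4, Itih2 and Alas1 lower in aged sections. Young and aged values did not overlap in 194 genes (1.38%), where chance gives 2.86%.

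Markers of oocytes, theca and blood vessels were lower in aged whole sections as groups, and markers of granulosa cells were higher, by camera with a preset correlation. None of these calls held with an estimated correlation (adjusted p = 0.519 to 0.624 with an estimated correlation). Of 17 measured oocyte genes, 13 were lower, with a median log2 fold change of −0.80. This median was 0.06 without young section 1, with 10 of 17 higher, and −2.50 without aged section 3. Padi6, needed for the oocyte's cytoplasmic lattices, was at 46.3 ± 39.9 CPM in young and 13.3 ± 17.5 CPM in aged sections, and Zp3, a zona pellucida gene, was at 44.3 ± 36.9 and 15.9 ± 22.1 CPM. Aged section 3 carried these aged means, with 39.6 CPM of Padi6 and 49.0 CPM of Zp3 against at most 4.93 and 5.47 CPM in the other aged sections, and without it the log2 fold changes were −3.27 for Padi6 and −3.11 for Zp3. Without young section 1 they were −1.32 and −1.07. Endothelial genes were lower in 9 of 11 (median −0.36): Cldn5, of endothelial tight junctions, was at 95.8 ± 26.8 and 52.4 ± 17.8 CPM, and Egfl7, secreted by endothelium, at 229.8 ± 20.8 and 152 ± 24.3 CPM. Smooth muscle and pericyte genes were lower in 10 of 11 (median −0.45), with Rgs5 at 53.5 ± 9.49 and 37.5 ± 9.20 CPM. Theca genes were lower in 7 of 8 (median −0.44), with Aldh1a1, a retinoic acid synthesis enzyme, at 974 ± 276 and 599.5 ± 172 CPM. Stromal fibroblast genes were lower in 9 of 12 (median −0.26), with Mfap4 at 138 ± 26.1 and 76.8 ± 33.7 CPM. Granulosa genes were higher in 15 of 16 (median 0.70): Inhba, an activin and inhibin subunit, was at 62.95 ± 48.7 and 257 ± 258 CPM, and Cyp19a1, aromatase, at 5.06 ± 5.15 and 34.2 ± 39.6 CPM (n = 4 per age). Without aged section 1 their log2 fold changes were 1.31 for Inhba and 1.91 for Cyp19a1, against 2.12 and 2.91 with it.

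Camera with a preset correlation of 0.01 called these 6 lists at adjusted p = 8.30e-07 (oocyte), 7.84e-06 (endothelium), 0.000521 (smooth muscle and pericyte), 0.000521 (theca), 0.00135 (stromal fibroblast) and 0.000394 (granulosa). Not one call held with an estimated correlation: adjusted p = 0.624 with an estimated correlation for the oocyte, stromal fibroblast and granulosa lists, 0.519 for endothelium and theca, and 0.533 for smooth muscle and pericyte. No single member of these lists passed over all genes or adjusted over the list alone. The granulosa call ended without aged section 3 (adjusted p = 0.0797), and the fibroblast call ended without aged section 3 (0.0820) or aged section 4 (0.242).

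Genes of plasma cells, neutrophils, T cells and red cells were higher in aged whole sections as groups, by camera with a preset correlation. None of these calls held with an estimated correlation (adjusted p = 0.142 to 0.767 with an estimated correlation). B and plasma cell genes were higher in 8 of 10 (median log2 fold change 1.61). The immunoglobulin gene Ighg2b was at 3.61 ± 3.04 CPM in young and 53.6 ± 79.8 CPM in aged sections, and Jchain, which joins secreted immunoglobulin chains, at 10.4 ± 9.98 and 45.3 ± 51.4 CPM. Without aged section 2 the log2 fold change fell from 3.99 to 2.02 for Ighg2b and from 2.36 to 1.21 for Jchain, and the list median to 0.46. Neutrophil genes were higher in 4 of 4 (median 1.35), with S100a8, a subunit of calprotectin, at 0.90 ± 0.366 and 3.02 ± 1.18 CPM and its partner S100a9 at 1.24 ± 0.865 and 4.32 ± 2.06 CPM. Of the 4, Mmp9 was higher through aged section 2 alone (71.5 CPM, against at most 8.09 CPM in the other aged sections). Without that section its log2 fold change turned from 1.01 to −1.12, and the list median was 1.16. T and NK cell genes were higher in 10 of 12 (median 0.38), with Cd3e at 1.18 ± 1.03 and 2.36 ± 1.60 CPM. The log2 fold change of Cd3e was 1.24, or 0.72 without aged section 4 and 1.91 without young section 3. Erythrocyte genes were higher in 5 of 5 (median 0.58), with Hba-a1 at 40.1 ± 37.9 and 61.7 ± 45.2 CPM, whose log2 fold change fell from 0.67 to 0.17 without aged section 1. Adjusted over the list alone, S100a8 and S100a9 passed in edgeR, against 0 neutrophil genes over all genes, and no member of the other lists named here did. Camera gave adjusted p = 0.000394 for B and plasma cells, 6.72e-05 for neutrophils, 0.00683 for T and NK cells and 0.0240 for erythrocytes. With an estimated correlation it gave adjusted p = 0.624 with an estimated correlation for B and plasma cells and for erythrocytes, 0.142 for neutrophils and 0.767 for T and NK cells. Without aged section 2 the calls for B and plasma cells (adjusted p = 0.189), T and NK cells (0.374) and erythrocytes (0.262) ended. The T and NK call also ended without young section 2 (0.13), aged section 1 (0.0569) or aged section 4 (0.0515), and the erythrocyte call without young section 3 (0.186), young section 4 (0.18) or aged section 1 (0.163).

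Genes of cholesterol synthesis and the genes of the mitochondrial genome were higher in aged whole sections as groups, by camera with a preset correlation. Neither call held with an estimated correlation (adjusted p = 0.624 and 0.519 with an estimated correlation). All 22 measured cholesterol genes were higher (median log2 fold change 0.76): Hsd17b7, which acts in both cholesterol and oestradiol synthesis, was at 226 ± 112 CPM in young and 813 ± 951 CPM in aged sections. Without aged section 4 its log2 fold change fell from 1.88 to 0.57, and the median of the list to 0.40. Insig1, a sterol-sensing regulator of the pathway, was at 68.8 ± 39.8 and 115 ± 48.7 CPM. All 13 mitochondrially encoded genes were higher (median 0.94), with mt-Nd3 at 73.1 ± 38.6 and 206 ± 156 CPM. Among the others, mt-Co2 was at 925 ± 499 and 1919 ± 823 CPM and mt-Atp6 at 1329 ± 571 and 2608 ± 1301 CPM (n = 4 per age). Aged spots also held fewer UMIs, 12692 ± 2725 against 20384 ± 5543. Camera gave adjusted p = 1.33e-07 for cholesterol genes and 6.00e-14 for mitochondrially encoded genes, against 0.624 and 0.519 with an estimated correlation. No member passed over all genes or adjusted over the list alone. Across all 33 lists tested in whole sections camera called 12, fry called 0 (lowest adjusted p = 0.123), and 21 of the 35 splits of the 8 sections, the real one included, gave as many calls. The count of called lists was 20 without aged section 3 and otherwise 10 to 15 with a section left out.

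The remaining 21 lists were not called in whole sections. Among cell type markers, corpus luteum genes were higher in 9 of 12 (adjusted p = 0.870), surface epithelium genes in 6 of 11 (0.739), macrophage genes in 8 of 11 (0.939) and genes of lipid-laden macrophages in 9 of 12 (0.0990). Oviduct epithelium genes were higher in 1 of 8 (0.929), and this list alone was added with the capture area as a block, as lower in aged sections (adjusted p = 0.00325; without the block, adjusted p = 0.982 with an estimated correlation). Among immune processes, higher members numbered 8 of 9 for MHC class II (0.402), 9 of 12 for MHC class I (0.0796), 8 of 13 for complement (0.959), 13 of 18 for interferon response (0.136) and 13 of 20 for cytokines and chemokines (0.618). Extracellular matrix genes were higher in 9 of 23 (0.366), steroidogenesis genes in 12 of 18 (0.796), nuclear genes of oxidative phosphorylation in 18 of 34 (0.712) and cytosolic ribosome genes in 21 of 45 (0.929). Cell cycle genes were higher in 12 of 24 (0.508), DNA repair genes in 16 of 20 (0.915), senescence genes in 10 of 15 (0.712) and antioxidant genes in 14 of 22 (0.948). Chaperone genes were higher in 5 of 18 (0.896), immediate early genes in 8 of 15 (0.779) and lysosome genes in 10 of 19 (0.948). The median and the direction of the test differed in sign for corpus luteum, surface epithelium, cytokines, oxidative phosphorylation, cell cycle, antioxidant, immediate early and ribosome lists. The cumulus and adipocyte lists had 3 measured members each, too few for a test, of which 1 and 2 were higher. The adipocyte gene Fabp4, at 18.8 ± 14.1 and 69.3 ± 35.3 CPM, passed adjusted over the list alone in edgeR, but not over all genes.

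**Figure D3:**
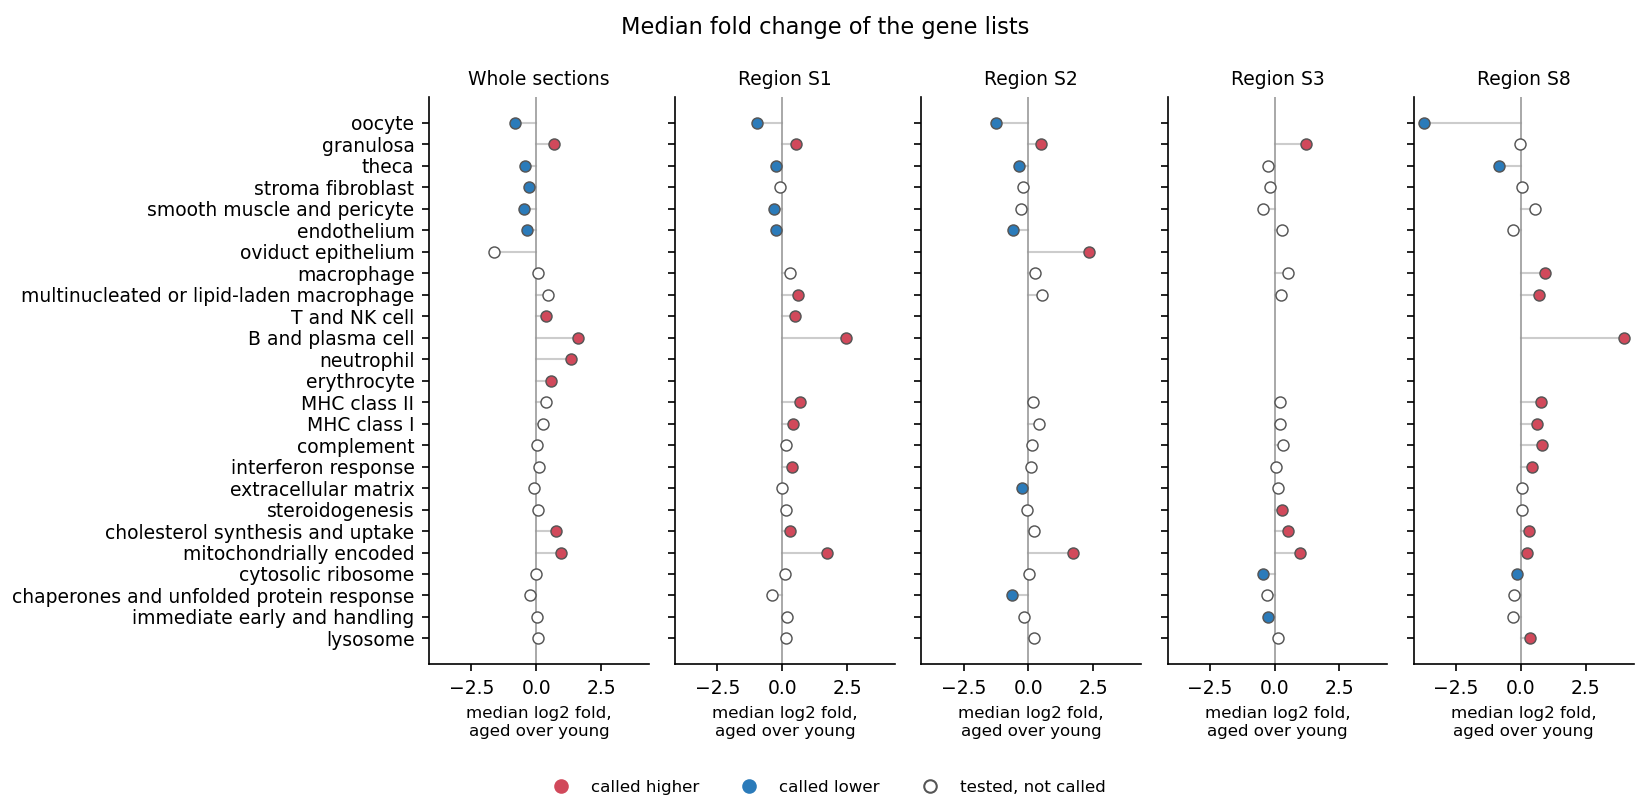
Median log2 fold change (aged over young) of the measured members of each gene list that camera called in at least 1 comparison, in whole sections and in regions S1, S2, S3 and S8, with filled red points for lists called higher, filled blue points for lists called lower and open points for lists not called. Mitochondrially encoded genes had a median of 0.94 in whole sections and 1.73 in S1, and oocyte genes a median of −0.80 in whole sections, or −2.50 without aged section 3, and −3.75 in S8, where aged section 3 was not tested.

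In region S1, led by Ccl21a and Agt, mitochondrially encoded, lymphocyte, antigen presentation, interferon and granulosa genes were higher in aged sections as groups, and oocyte and vessel genes were lower, by camera with a preset correlation. None of the calls held with an estimated correlation (adjusted p = 0.557 to 0.733 with an estimated correlation). The macrophage (10 of 11 higher, adjusted p = 0.0745), complement (7 of 12, 0.566) and cytokine (8 of 14, 0.801) lists were not called in S1. The S1 spots lay unequally among the regions centred within capture areas: 78.9% of those in young and 16.5% in aged sections lay in A1, led by Agt, and 0.228 and 49.2% in A4, led by immunoglobulin genes. S1 was thus not shown to be the same tissue at both ages. All 12 mitochondrially encoded genes were higher (median log2 fold change 1.73), with mt-Nd1 at 239.6 ± 93.1 CPM in young and 980.2 ± 748 CPM in aged sections (n = 4 per age). All 12 genes of lipid-laden macrophages were higher (median 0.60), with Acp5, a lysosomal phosphatase, at 25.7 ± 21.8 and 42.5 ± 3.55 CPM. T and NK cell genes were higher in 7 of 7 (0.49; Cd3g at 3.82 ± 2.80 and 11.3 ± 8.13 CPM) and B and plasma cell genes in 5 of 7 (2.46; Jchain at 8.08 ± 12.4 and 70.1 ± 107 CPM, whose log2 fold change fell from 4.05 to 1.63 without aged section 2). The B and plasma cell median was then 0.41, over the 6 members still tested. Antigen presentation followed, with 7 of 8 MHC class II genes (0.67) and 12 of 12 MHC class I genes (0.40) higher, B2m among them at 444 ± 82.2 and 602 ± 121 CPM. Interferon response genes were higher in 15 of 16 (0.36), with Ifi27l2a at 76.4 ± 9.12 and 157 ± 46.8 CPM. Granulosa genes were higher in 15 of 15 (0.54), with Inhbb at 18.6 ± 7.32 and 77.8 ± 53.2 CPM, and cholesterol genes in 20 of 22 (0.29). Oocyte genes were lower in 9 of 9 (−0.99), but without aged section 2 or young section 1 only 5 of 8 were lower (−0.30 and −0.54). Endothelial genes were lower in 10 of 11 (−0.23; Cldn5 at 176 ± 77.0 and 89.997 ± 29.3 CPM). So were smooth muscle and pericyte genes in 10 of 11 (−0.31; Myh11 at 263 ± 93.5 and 149.9 ± 44.5 CPM) and theca genes in 6 of 7 (−0.25).

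Camera called 13 of the 30 lists tested in S1. For immune lists it gave adjusted p = 3.30e-07 for lipid-laden macrophages, 0.00251 for T and NK cells and for MHC class I, 7.70e-05 for B and plasma cells, 0.0143 for MHC class II and 4.12e-06 for interferon response. For the others it gave adjusted p = 4.06e-20 for mitochondrially encoded genes, 0.000121 for granulosa, 1.89e-05 for cholesterol, 2.98e-05 for oocyte, 0.000265 for endothelium, 0.00148 for smooth muscle and 0.0144 for theca. Of the values with an estimated correlation, the lowest of the 13 was adjusted p = 0.557 with an estimated correlation, for mitochondrially encoded, lipid-laden macrophage, B and plasma cell and endothelial genes, and the highest 0.733, for MHC class II. With the capture area as a block, 18 lists were called in S1, these 13 among them. Without the block, 13 of the 35 splits of the sections, the real one included, gave as many list calls. Adjusted over the list alone, 12 mitochondrially encoded, 3 B and plasma cell, 2 adipocyte, 1 granulosa (Inhbb), 1 T and NK cell and 1 interferon gene passed in edgeR. Over all genes 0 of 11541 passed (362 at an unadjusted p under 0.05), with the smallest p for Slc15a2, a peptide transporter (chr16, 36750177 to 36784962), at 1.46 ± 0.312 and 15.1 ± 9.32 CPM (adjusted p = 0.158 in edgeR). Next came the metalloproteinase gene Mmp14 at 2.92 ± 0.942 and 11.1 ± 1.27 CPM and the nuclear RNA Malat1 at 212 ± 46.9 and 701 ± 352 CPM. DESeq2 passed 11 genes, edgeR without a filter on low counts 8, and edgeR with the capture area as a block 4: Fabp4, mt-Nd5 and Car3 as higher and Alas1 as lower. Without aged section 2 the unblocked count was 3, and no gene's age difference differed between S1 and the rest of the section (0 of 13562; 690 at an unadjusted p under 0.05, and 99 passing without the filter).

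In region S2, led by oocyte genes, the rise of BC048679 was the 1 change that passed over all genes. BC048679 had no counts in the 3 young sections tested and stood at 87.8 ± 16.3 CPM in the 3 aged sections, at least 167-fold higher against a floor of 3 counts over the young group (0.527 CPM; edgeR adjusted p = 0.00113). Oocyte genes were lower in 15 of 17 (median log2 fold change −1.27), with Padi6 at 351 ± 155 and 53.5 ± 27.5 CPM. Spots of S2 with at least 3 oocyte-list UMIs were 83.5% in young and 66.5% in aged sections, and fewer than 3 were found in 18 of 32 S2 spots of aged section 2, 5 of 88 of aged section 3 and 28 of 35 of aged section 4. Also on the list, Figla, a transcription factor of zona pellucida genes, was at 25.4 ± 7.77 and 2.74 ± 2.64 CPM. Its log2 fold change was −2.84, or −4.27 without aged section 3. Mitochondrially encoded genes were higher in 11 of 11 (1.72), with mt-Nd3 at 61.4 ± 14.7 and 297.6 ± 160.4 CPM. Chaperone genes were lower in 16 of 18 (−0.62; Hspe1, a mitochondrial chaperonin, at 813 ± 171 and 431 ± 43.8 CPM), and extracellular matrix genes in 14 of 21 (−0.26; Col4a2 at 304 ± 20.5 and 174 ± 28.8 CPM). Oviduct epithelium genes were higher in 4 of 4 (2.32), with Pax8, a transcription factor of the reproductive tract, at 0.496 ± 0.859 and 18.3 ± 7.01 CPM. The oviduct median ran from 1.64 to 4.84 with a section left out, and 25.3% of aged but 0.402% of young S2 spots lay in the area-centred region A21, led by oviduct epithelium genes. Granulosa genes were higher in 14 of 15 (0.49; Amh at 8.36 ± 2.93 and 16.7 ± 7.96 CPM, whose log2 fold change fell from 1.18 to 0.58 without aged section 3). Theca genes were lower in 7 of 7 (−0.37) and endothelial genes in 8 of 10 (−0.60). Of the theca genes, Cyp17a1 was at 296.6 ± 19.9 and 97.98 ± 106 CPM. Its log2 fold change of −1.62 ran from −2.56 (without aged section 4) to −1.13 (without aged section 2). Without aged section 3 the endothelial median was −0.10 and that of extracellular matrix genes turned to 0.05, and without young section 2 the chaperone median was −0.03. The age difference differed between S2 and the rest of the section for 4 of 12486 genes in edgeR. Plet1 (adjusted p = 0.00770) was at 3.22 ± 4.08 and 58.1 ± 71.5 CPM in S2 against 9.59 ± 13.2 and 4.39 ± 1.94 CPM elsewhere. Mme, the peptidase neprilysin (0.0310), was at 8.44 ± 3.72 and 63.7 ± 22.0 CPM in S2. Lcn2, an iron-trapping lipocalin (0.0456), was at 3.85 ± 0.807 and 43.0 ± 29.4 CPM, and the carboxylesterase gene Ces1d (0.0412) at 0.496 ± 0.859 and 13.4 ± 4.45 CPM. In aged S2 spots, 74.5% of the UMIs of BC048679, Plet1, Mme, Ces1d and Lcn2 lay in spots with fewer than 3 oocyte-list UMIs.

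Of the 10139 genes tested in S2, 637 had an unadjusted p under 0.05. Those nearest to passing included Cldn3, an epithelial tight junction gene, at 5.78 ± 1.21 and 29.7 ± 1.81 CPM and C3, the central complement gene, at 26.5 ± 5.72 and 148 ± 66.6 CPM (both edgeR adjusted p = 0.0903; n = 3 per age). The count of called genes was 2 without aged section 2, 12 without aged section 3, 5 without aged section 4, 33 in DESeq2, 208 without the filter and 0 with regions formed at resolution 0.5. With the capture area as a block, on 2 pairs, 6 genes rose, BC048679, Podxl, Igkc, Igha, Jchain and Ighg2b. Young and aged values did not overlap in 1164 genes (11.5%), where chance gives 10%. Camera called 8 of 29 lists, at adjusted p = 1.70e-10 for oocyte, 4.36e-17 for mitochondrially encoded, 0.000229 for chaperone, 0.000250 for extracellular matrix, 1.59e-05 for oviduct epithelium, 0.000966 for granulosa, 0.0292 for theca and 0.00507 for endothelial genes. All 8 were lost with an estimated correlation, from adjusted p = 0.557 with an estimated correlation (mitochondrially encoded and oviduct epithelium) to 0.733 (chaperones, extracellular matrix and endothelium). The fit with the block, which also dropped the sections without a partner, did not call theca (adjusted p = 0.0582), endothelium (0.141) or extracellular matrix (0.181), and left too few oviduct epithelium genes to test. On 2 pairs and by the preset correlation alone, it added 10 lists. These were corpus luteum as lower, and macrophage, lipid-laden macrophage, B and plasma cell, MHC class I, MHC class II, complement, interferon, cholesterol and lysosome as higher. Adjusted over the list alone, 8 oocyte and 2 chaperone genes fell, and 11 mitochondrially encoded and 2 oviduct epithelium genes rose. So did 2 surface epithelium (with 1 fall), 2 B and plasma cell, 1 complement and 1 immediate early gene, none of these passing over all genes in edgeR.

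In region S3, led by granulosa genes, granulosa, steroid and cholesterol genes were higher in aged sections as groups and ribosomal protein genes were lower, by camera with a preset correlation. None of the calls held with an estimated correlation (adjusted p = 0.606 to 0.843 with an estimated correlation). Granulosa genes were higher in 12 of 15 (median log2 fold change 1.19), with Nap1l5 at 341 ± 154 CPM in young and 1134 ± 759.8 CPM in aged sections. Of the S3 spots, 78.97% in young and 22.4% in aged sections lay in the area-centred region A2, and 9.59 and 67.2% in A14, led by granulosa genes with Nap1l5 among them, so that S3 was not shown to be the same tissue at both ages. Slc18a2, a vesicular monoamine transporter on the same list, was at 182 ± 109 and 26.1 ± 25.7 CPM (n = 4 per age). Steroidogenesis genes were higher in 17 of 18 (0.26), with Hsd3b1, which makes progesterone, at 4216 ± 1872 and 9019.9 ± 926 CPM. Cholesterol genes were higher in 22 of 22 (0.51), with Fdft1, squalene synthase, at 87.5 ± 36.0 and 145 ± 50.5 CPM. Mitochondrially encoded genes were higher in 11 of 11 (0.99), with mt-Nd4 at 628 ± 112 and 1384 ± 1369 CPM. Aged section 3 carried this rise, since without it the median was 0.22 and the log2 fold change of mt-Nd4 fell from 1.04 to 0.22. Ribosomal protein genes were lower in 44 of 45 (−0.43; Rps18 at 42.2 ± 10.9 and 26.7 ± 9.35 CPM), and immediate early genes in 8 of 12 (−0.26; Fos at 71.9 ± 23.01 and 34.0 ± 20.3 CPM). Camera called these 6 of 26 lists at adjusted p = 0.000708 (granulosa), 0.00278 (steroidogenesis), 1.31e-08 (cholesterol), 0.00632 (mitochondrially encoded), 3.07e-07 (ribosome) and 0.0258 (immediate early). With an estimated correlation it gave adjusted p = 0.646 with an estimated correlation for granulosa, 0.606 for steroidogenesis and cholesterol, 0.843 for mitochondrially encoded, 0.733 for ribosome and 0.694 for immediate early genes. With the capture area as a block, 10 lists were called in S3, these 6 among them. Without the block, as many list calls came from 30 of the 35 splits. Adjusted over the list alone, 8 granulosa genes rose and Slc18a2 fell in edgeR, and none passed over all genes. By the same adjustment 2 senescence genes rose and 1 fell, 1 cytokine gene rose and 2 fell, and 1 gene each of the cumulus, adipocyte and B and plasma cell lists rose. Of the smooth muscle and lipid-laden macrophage lists, 1 gene each fell.

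Single genes of S3 came close to the threshold without passing. Itih2 (chr2, 10094593 to 10131396) was at 57.9 ± 11.5 CPM in young and 10.1 ± 5.87 CPM in aged sections (n = 4 per age; edgeR adjusted p = 0.0544). Tmem141 (chr2, 25620067 to 25622005) was at 32.4 ± 7.90 and 80.4 ± 8.44 CPM (adjusted p = 0.0544). Plagl1, an imprinted transcription factor gene (chr10, 13060504 to 13131694), was at 66.8 ± 22.7 and 15.2 ± 1.68 CPM (adjusted p = 0.0572). Rgs11, a regulator of G protein signalling (chr17, 26202951 to 26211324), was at 91.5 ± 21.5 and 34.1 ± 6.98 CPM (0.0618). Over all genes 0 of 9185 passed in edgeR (793 at an unadjusted p under 0.05), against 51 in DESeq2, 247 without the filter and 3 with RLE scaling. With the capture area as a block 7 passed, among them Plagl1 and Wt1 as lower. The count was 55 without young section 3, 55 without aged section 3, 20 without aged section 2 and 1 without young section 1. No gene's age difference differed between S3 and the rest in edgeR (0 of 12613, 1087 at an unadjusted p under 0.05, and 145 passing without the filter).

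In region S8, led by Upk3b and Krt19, antigen presentation, complement, interferon and macrophage genes were higher in aged sections as groups, and oocyte genes were lower, by camera with a preset correlation. None of the calls held with an estimated correlation (adjusted p = 0.557 to 0.938 with an estimated correlation), and 13 of the 35 splits gave as many. Of the S8 spots, 73.9% in young and 76.5% in aged sections lay in the area-centred region A10. However, 8.11 and 21.2% lay in A22, led by smooth muscle genes, and 14.4% of the young but none of the aged in A2. S8 was thus not shown to be the same tissue at both ages. MHC class I genes were higher in 11 of 11 (median log2 fold change 0.62), with H2-D1 at 393 ± 251 CPM in 4 young sections and 1128 ± 637 CPM in the 3 aged sections with enough spots. MHC class II genes were higher in 6 of 7 (0.77; H2-Aa at 174 ± 99.7 and 335 ± 133 CPM) and complement genes in 9 of 10 (0.82; C1s1 at 111 ± 71.6 and 240.5 ± 36.8 CPM). Interferon response genes were higher in 12 of 12 (0.44; Ifi27l2a at 113 ± 43.3 and 256 ± 50.0 CPM) and macrophage genes in 7 of 7 (0.95; C1qa at 95.3 ± 46.8 and 188 ± 39.9 CPM). So were genes of lipid-laden macrophages in 6 of 9 (0.68, or 0.03 without aged section 4) and lysosome genes in 17 of 19 (0.34; Ctsd at 555 ± 171 and 940.5 ± 179 CPM). B and plasma cell genes were higher in 3 of 4 (3.96), with Ighg2b at 3.79 ± 4.61 and 55.8 ± 27.5 CPM and Igha at 19.1 ± 15.3 and 407 ± 483 CPM, whose log2 fold change fell from 4.48 to 2.87 without aged section 2. Cholesterol genes were higher in 20 of 22 (0.32) and mitochondrially encoded genes in 10 of 11 (0.24). Oocyte genes were lower in 7 of 7 (−3.75, or −3.41 with Khdc3 at its bound), with Padi6 at 42.2 ± 27.9 and 0.832 ± 1.44 CPM. Aged section 3, whose share of spots with oocyte transcripts was the highest of all sections (18.2%), was not tested in S8. Khdc3 was at 27.3 ± 18.5 CPM against no counts in aged sections, at least 10.6-fold lower against a floor of 3 counts over the aged group (2.58 CPM). Theca genes were lower in 5 of 5 (−0.83; Aldh1a1 at 1012 ± 186 and 649.8 ± 213 CPM) and ribosomal protein genes in 41 of 44 (−0.13, or 0.00462 without young section 1).

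Camera called these 13 of 29 lists in S8 at adjusted p = 1.93e-08 (MHC class I), 3.65e-05 (MHC class II), 7.71e-07 (complement), 1.59e-05 (interferon), 1.94e-06 (macrophage and lysosome), 0.0335 (lipid-laden macrophage), and 2.98e-05 (B and plasma cell). For the rest it gave adjusted p = 0.000229 (cholesterol), 0.0411 (mitochondrially encoded), 0.00103 (oocyte), 0.000290 (theca) and 0.0259 (ribosome). With an estimated correlation they ran from adjusted p = 0.557 with an estimated correlation (complement, interferon, B and plasma cell, theca) to 0.938 (ribosome). With the capture area as a block and the preset correlation, 19 lists were called, these 13 among them. Adjusted over the list alone, 7 oocyte genes fell and 3 B and plasma cell, 4 complement, 2 interferon, 2 MHC class I and 1 MHC class II genes rose in edgeR. So did 2 of 2 erythrocyte genes (median 1.55), 2 of 2 adipocyte genes (2.20), 1 senescence and 1 antioxidant gene. Over all genes 0 of 8328 passed (398 at an unadjusted p under 0.05), against 5 in DESeq2, 87 without the filter, 9 without young section 3 and 1 without young section 2. The age difference differed between S8 and the rest of the section for 7 of 13036 genes in edgeR. Krt19, an epithelial keratin (adjusted p = 0.0187), was at 184 ± 102 and 386 ± 142 CPM in S8 against 14.3 ± 7.67 and 8.90 ± 2.32 CPM elsewhere. Lhx9, a gonadal transcription factor (0.0197), was at 71.0 ± 48.5 and 173 ± 91.3 CPM in S8. Igha (0.0187), Igkc (0.0440) and Cyp2s1 (0.0440) also had a more positive log2 age difference in S8 than elsewhere, and Cst8 (0.0218) and Slpi (0.0421) a more negative one. The last 2 changed mainly outside S8. Slpi was at 16.8 ± 14.6 and 15.9 ± 14.0 CPM in S8 against 2.29 ± 2.21 and 20.9 ± 30.6 CPM elsewhere. Cst8 was at 88.8 ± 112 and 67.4 ± 36.4 CPM in S8 against 178 ± 199 and 485 ± 302 CPM elsewhere. Krt19 and Lhx9 were among the genes that lead the region.

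With the capture area as a block, S8 gave 136 rises and 84 falls, on 3 pairs and with 2 residual degrees of freedom. The rises held 6 MHC class I, 4 MHC class II, 4 complement, 4 lysosome, 7 cholesterol, 3 macrophage and 3 B and plasma cell genes, and the falls held 7 oocyte and 3 chaperone genes. The 3 pairs leave out area 3, whose aged section had too few S8 spots. In whole sections, area 3 alone had a higher share of spots with oocyte transcripts in its aged section (18.2 against 0.384%). The falls of oocyte genes thus come from the areas where that share was lower in the aged section. Among the falls were also Apoa1, Apoa4, Slc38a5, Cables1 and Tdrd5, leading genes of region A2, where 14.4% of young but none of the aged S8 spots lay. A different makeup of S8 at each age thus stays open for these calls. Igkc, the kappa light chain gene, was at 55.2 ± 62.5 CPM in 4 young and 893 ± 974 CPM in 3 aged sections (blocked log2 fold change 4.89 ± 0.30; edgeR adjusted p = 2.75e-09). H2-Q7, an MHC class I gene, rose (2.55 ± 0.51; 10.1 and 36.8 CPM; adjusted p = 0.00839), as did Fabp4, a fatty acid binding protein (2.51 ± 0.47; adjusted p = 0.00514). Padi6 fell with a change of −5.78 ± 0.66 (adjusted p = 3.98e-05), Dppa3, a maternal factor of the oocyte, with −4.87 ± 0.59 (37.7 and 1.43 CPM; 5.30e-05) and Ooep with −4.24 ± 0.50 (62.3 and 6.30 CPM; 4.73e-05). The blocked fit left out young section 3, where Padi6 was at 1.53, Dppa3 at 0 and Ooep at 4.57 CPM, within or near the aged values. The rises of Igkc and H2-Q7 have the same limit. In young section 3 Igkc was at 146 CPM, against 141 CPM in aged section 4. H2-Q7 was at 22.9 CPM there, against 22.5 and 19.7 CPM in aged sections 1 and 2. These falls and rises are thus shown only without young section 3. On the same 6 sections without the block, Padi6 also passed (log2 fold change −5.73, edgeR adjusted p = 0.00491). For the other genes of these falls and rises, the effects of that omission and of the block were not set apart. On all 7 sections without the block, edgeR gave adjusted p = 0.948 for Padi6 and Ooep, 0.959 for Dppa3, 0.462 for Igkc and Fabp4 and 0.977 for H2-Q7. The other 3 swaps of the ages within areas gave 0 genes each. Without the block the count was 9 on the same 6 sections, which leave out young section 3, and 0 on all 7.

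**Figure D4:**
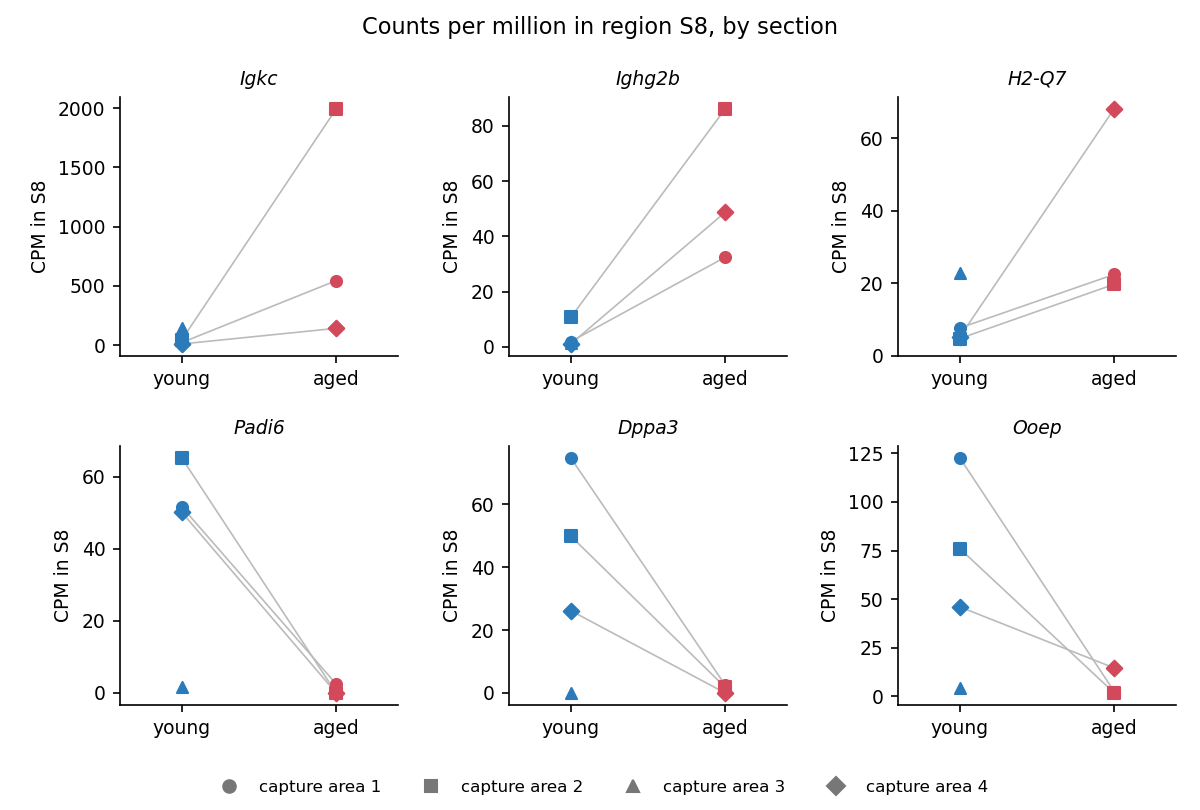
Expression in region S8 (CPM, linear axis) of Igkc, Ighg2b, H2-Q7, Padi6, Dppa3 and Ooep in each section with enough spots, with lines joining the sections of a capture area. Aged section 3 had too few spots. Igkc was at 55.2 ± 62.5 CPM in young and 893 ± 974 CPM in aged sections, and Padi6 at 42.2 ± 27.9 and 0.832 ± 1.44 CPM.

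The share of spots in a region did not pass between ages for any region. The smallest possible p was 0.0286 in these exact permutation tests. After adjustment over 22 or 16 regions a region could pass only if many reached that p together, so that not passing says little. Of the regions centred within capture areas, A1 held 27.1 ± 8.56% of the spots of young sections and 4.78 ± 6.35% of aged sections (exact permutation p = 0.0286, n = 4 per age; adjusted p = 0.629 over 22 regions). A4, led by immunoglobulin genes, held 0.0926 ± 0.185% and 15.4 ± 15.0% (exact permutation p = 0.143). Of the regions centred within sections, S10, whose spots had a median of 2825 UMIs, held 0.434 ± 0.0823% and 8.86 ± 3.49% (exact permutation p = 0.0286; adjusted p = 0.457 over 16 regions). Over 90% of a region's spots lay in a single section for 7 of the 22 regions and for 4 of the 16.

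Spots with oocyte transcripts, after thinning each spot to 2000 UMIs, were 12.9, 4.40, 0.384 and 6.84% of the young sections and 0.337, 1.46, 18.2 and 0.794% of the aged sections. The share was lower in the aged section of 3 of 4 areas and higher in area 3. Mean shares were 6.12 ± 5.22% and 5.19 ± 8.67% (exact permutation p = 0.83, n = 4 per age), a difference within the spread of the sections. Without aged section 3 the aged mean was 0.863 ± 0.564% (exact permutation p = 0.143). Without young section 1 or any of the other aged sections, the difference turned to the aged side, by 0.318 to 1.32 percentage points. The difference depended on the measure: spots with at least 10 oocyte-list UMIs were 1.38 ± 1.497% in young and 0.108 ± 0.216% in aged sections (exact permutation p = 0.143, n = 4 per age). Without thinning, spots with at least 3 such UMIs were 33.1 ± 23.3% and 17.2 ± 20.8% (exact permutation p = 0.343, n = 4 per age). Spots with under 2000 UMIs, left out here, were 1.09% of young and 6.28% of aged spots.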

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

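The tests of the mitochondrial share at matched UMIs, of region S10, of the splits of list calls and of the swaps within areas in S8 were set before their results were seen, and all other tests in this part were chosen after the result was seen.

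Mitochondrially encoded genes were higher in aged sections, in 13 of 13 members in whole sections. Fewer UMIs per spot as the whole cause is argued against: among S1 spots of 5000 to 15000 UMIs the age difference in the mitochondrial share was 1.04 times that over all S1 spots, and 0.969 to 1.18 with each section left out. A different makeup of the sections stays open: the list's median log2 fold change was 1.73 in S1 and 1.72 in S2 against 0.94 in whole sections, but 0.99 in S3, or 0.22 without aged section 3, and 0.24 in S8, tested without that section, and 78.9% of young but 16.5% of aged S1 spots lay in A1. The share in S1 varied widely between aged sections (0.459 ± 0.170% against 1.70 ± 1.70%, exact permutation p = 0.143, n = 4 per age). The age of the animals and the handling of single ovaries may each account for it, and neither was tested.

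In region S2, BC048679, Plet1, Mme, Ces1d and Lcn2 were higher in aged sections or differed there from the rest of the section. Spots that hold few oocyte transcripts and were grouped into S2 are a candidate source: 74.5% of the UMIs of these 5 genes in aged S2 spots lay in spots with under 3 oocyte-list UMIs. That share exceeded those spots' share of all UMIs in 3 of 3 aged sections (91.2 against 45.7%, 59.0 against 3.95% and 92.6 against 75.5%). Outside S2, BC048679 was at 0.611 ± 0.513 CPM in young and 5.26 ± 4.45 CPM in aged sections, with overlapping values (exact permutation p = 0.143, n = 4 per age), so that a rise limited to S2 and a wider rise both stay open. Age itself stays open as an explanation and was not tested.

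Aged sections had fewer UMIs per spot. Sequencing depth of the libraries is argued against, since the sections of an area shared a library and the aged to young ratio was under 1 in 4 of 4 areas, with a mean of 0.639 ± 0.142 (SD, n = 4). The low-UMI spots of region S10 are argued against as the whole cause, since 0.877 of the difference remained without them (0.810 to 0.9004 with each section left out; 20425 against 13683 UMIs, exact permutation p = 0.0857, n = 4 per age). Makeup stays open: within S1 the ratio was 0.671 ± 0.219 and under 1 in 4 of 4 areas, but within S3 it was 0.830 ± 0.415 and under 1 in 2 of 4 areas, and the spots of S1 and S3 lay in unlike area-centred regions at each age. Less RNA per area of aged tissue, tissue quality or permeabilisation may account for it, and none of these was tested.

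Chance was not excluded for any count above 0 that had enough splits. Where the real count was 0, all 35 of 35 splits give as many by construction, which tests nothing: genes of whole sections, S1, S3 and S8 (highest other counts 68, 13, 105 and 32) and genes with an age difference that differed between region and rest in S1 and S3 (37 and 62). In S8 as many such genes came from 6 of 35 splits (real 7, highest other 16). As many list calls were found in 21 of 35 splits for whole sections (real 12, highest other 21), 13 of 35 for S1 (13 and 19), 30 of 35 for S3 (6 and 16) and 13 of 35 for S8 (13 and 20). Among the 8 splits that part the ages as the real one does with respect to the pairs, as many list calls came from 7 for whole sections, 3 for S1, 7 for S3 and 4 for S8. As many interaction genes in S8 came from 1 of these, the real one, the others giving at most 6. The other splits put paired sections together and so compare areas in part. The counts of 68 and 62 genes came from the same split, which exchanges the ages of area 3 alone and gave 13 genes in S1 and 23 in S3. It also gave 22 genes whose age difference differed between S1 and the rest. In S8, which lacks aged section 3, the split that moves young section 3 alone to the aged side gave 27 genes. The real ages gave 0 in each of these comparisons. Splits with 68, 105 or 62 genes leave room for a structure of the sections besides age, or for exchanged labels in area 3. Which of these sets them apart was not tested.

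For S2 the 10 splits are too few for a share under 0.05: the real counts were 1 gene, 8 lists and 4 interaction genes, the highest others were 1, 22 and 8, and as many came from 2, 8 and 2 splits. For S8 with the capture area as a block, the 4 swaps of ages are too few as well, with 220 genes in the real one, 0 in the highest other and 1 swap with as many, the real one. With that block, the swap of area 3 alone gave 49 genes in S1, 54 in S3 and 11 in whole sections, against 4, 7 and 0 for the real ages.

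A single section lay far from the other 3 of its group in 30 of the 253 groups of 4 examined, of which chance alone gives about 12.7 (1 in 20); the values follow. Aged section 3 stood apart in its oocyte share (18.2% of spots) and, in whole sections, in CPM of Padi6 (39.6), Zp3 (49.0), Zp1 (14.4), BC048679 (46.8) and Rgs5 (51.1), and in S1 in Zp3 (42.6) and Trdc (0). Aged section 2 stood apart in Mmp9 (71.5 CPM) and, in S1, in Jchain (229 CPM), aged section 1 in Aldh1a1 (857 CPM), and aged section 4 in the share of region A1 (14.3%). Young section 3 stood apart in the share of region A4 (0.370%), in whole-section CPM of Cd4 (2.99), Mmp9 (33.7) and Insig1 (128), in S1 in Trdc (5.70), Ifi44 (5.70), Cldn5 (291), Acp5 (58.3), Atp6v0d2 (30.4) and Jchain (26.6), in S3 in Hsd17b1 (381) and in S8 in H2-D1 (769). Young section 2 stood apart in BC048679 (1.25) and Aldh1a1 (561) in whole sections and in Ighg2b (10.7) in S8, and young section 1 in Hbb-bt (11.99) in whole sections, Nlrp5 (12.1) in S1 and mt-Nd4 (794) in S3.

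The age difference of some genes differed between a region and the rest of the section by the interaction test in edgeR. In S2 the difference of log2 fold changes was 5.03 for Plet1, 2.75 for Mme, 6.08 for Ces1d and 4.03 for Lcn2. In S8 it was 1.92 for Igha, 1.68 for Krt19, 1.76 for Lhx9, 1.82 for Cyp2s1, 1.82 for Igkc, −1.81 for Cst8 and −3.52 for Slpi.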

How the results depend on the processing

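The section-centred regions with their resolutions 0.3 and 0.5, and scaling by library size alone, were chosen after seeing the data; the other alternatives were set before. Of the alternatives of results that answer a comparison, 120 left the result as it was, 34 moved a count or value, 3 brought it past the threshold and 8 turned its direction. Some of the 120 could not have passed: the smallest possible p of the sign-flip tests was 0.125, and region shares could pass only if many reached the smallest p together. Of those of single genes and lists, 2145 left it as it was, 113 brought it past the threshold, 79 took it below and 5 turned its direction. No gene of whole sections passed in edgeR under any alternative run there, while DESeq2 passed 6. With the capture area as a block the counts of genes were 4 in S1, 6 in S2, 7 in S3 and 220 in S8, with DESeq2 11, 33, 51 and 5, and without the filter on low counts 8, 208, 247 and 87. Without the filter, the counts of genes whose age difference differed between region and rest were 99 in S1, 180 in S2, 145 in S3 and 84 in S8. RLE scaling gave 3 genes in S3, and resolution 0.5 gave 0 in S2. Called lists numbered 0 with an estimated correlation and 0 with fry in whole sections, and 0 with an estimated correlation and 61 with the block in regions (40 without). For each of these the cause was not tested. With a section left out, called genes ranged from 0 to 3 in S1, 1 to 12 in S2, 0 to 55 in S3 and 0 to 9 in S8, and called lists in whole sections from 10 to 20. The difference in oocyte share ranged from −5.26 to 1.32 percentage points, in median UMIs from −9489.9 to −5113 (without young section 2, exact permutation p = 0.0571), in spots from −317.5 to −185.5, in median genes from −1443 to −1094, in the mitochondrial share from 0.740 to 1.76 and in the ribosomal share from −1.86 to 1.25 percentage points. The log2 fold change of Mmp9 ranged from −1.12 (without aged section 2) to 1.87. In limma with equal weight of regions S1 and S3, the log2 fold change turned to −0.24 for Calb2, −0.80 for Mmp9, −0.0112 for Hba-a2 and −0.32 for Alas2. That fit leaves out the spots of all other regions. Of the 148 gene entries that are members of called lists or have the smallest p, named in the text or not, 35 moved by over 1.5-fold with a section left out, 4 turned sign and 56 passed under some alternative alone. Among all 234 entries that the rule takes, 27 turned sign under some alternative. The planned gene tests of regions at resolutions 0.4 and 1.0 and the removal of border spots were not run, as no area-centred region met the minimum and 0 spots lay within 3 spacings of the other section; S8 had no match to test at resolution 0.5. The shallowest section held 2777948 UMIs, and thinning all sections to it left 0 genes passing in whole sections (354 of 11979 at an unadjusted p under 0.05), so that depth was not set apart from the spread between animals as a limit. At these depths, folds of 2 were found in 20.9 to 46.3% of simulated genes in tests of whole sections and regions, and in 28.4 to 56.7% in tests of a region against the rest.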

Other observations

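The values in this part were all chosen after seeing the data, and the tests by region as well. Regions differed in a pair of genes of the corpus luteum list, and whether these regions are luteal tissue was not tested. Lhcgr, the receptor for luteinizing hormone, was at 1335 CPM in region S5 and 1005 CPM in S11, where Akr1c18, which breaks down progesterone, was at 1460 and 1652 CPM. In regions S9, S12, S14 and S15, Lhcgr was at 87.1, 65.8, 157 and 60.8 CPM, and Akr1c18 at 16222, 16103, 27505 and 17200 CPM. In S4, S6 and S7, Lhcgr was at 114, 91.3 and 61.9 CPM, and Akr1c18 at 8049, 9042 and 5783 CPM. S12 lay mostly in 1 young section (96.6% of its spots) and S14 in 1 aged section (100%), so that no age comparison was made within them. S14 also led in Timp1, an inhibitor of matrix proteases, at 26172 CPM, and in Spp1, osteopontin, at 7360 CPM. Region S7, with 90.3% of its spots in aged section 2, led in Mmp9, a matrix protease, at 136 CPM, and region S16, with 85.2% of its spots in young section 2, in oviduct epithelium genes such as Foxj1, of ciliated cells (721 CPM), and Ovgp1, of secretory cells (1328 CPM). Region S10, found mostly in aged sections, led in Malat1 (9297 CPM), Jchain (342 CPM) and mt-Co2 (6583 CPM).

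Outside the oocyte-led region, oocyte transcripts were compared by region. In S8, 57.7 ± 38.5% of the spots of 4 young sections and 4.55 ± 7.87% of those of 3 aged sections, aged section 3 left out, held at least 3 oocyte-list UMIs without thinning (exact permutation p = 0.0857, adjusted p = 0.171 over 6 comparisons), at medians of 25478 and 14301 UMIs per spot. By the same measure the shares were 40.3 ± 20.96% and 11.3 ± 10.5% in S3 (exact permutation p = 0.0571, n = 4 per age) and 25.5 ± 16.9% and 12.9 ± 19.7% in S1 (exact permutation p = 0.314). Spots with at least 1 such UMI after thinning to 2000 were 45.6 ± 28.3% and 9.97 ± 15.0% in S8 (exact permutation p = 0.114). By this measure they were 25.6 ± 10.8% and 9.65 ± 5.28% in S3 (exact permutation p = 0.0286, adjusted p = 0.171) and 20.4 ± 8.96% and 19.8 ± 19.1% in S1 (exact permutation p = 0.971). No comparison passed after adjustment, where several of the 6 would have had to reach the smallest possible p of 0.0286 (exact permutation test) together to pass.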
